A study of Mus musculus with 46 samples.

How the data were processed

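RNA of adult mouse hearts, perfused before extraction with Trizol per the labels' protocols, was sequenced in 46 libraries. Per the labels, 26 libraries of a time course after tamoxifen were made with the NEBNext Ultra II Directional kit after poly(A) selection, and 20 libraries of a cross between floxed Lmna and cGas null mice with the QuantSeq 3' FWD kit. The NEBNext libraries cover whole transcripts, so long genes collect more reads than short ones. QuantSeq yields a tag per transcript near its 3' end, so gene length plays little part and a gene whose 3' end is poorly annotated is undercounted. The labels give the genotype, the time, the sex and a sequencing pool for each library, and each title carries a number of its own. They do not state that each library came from a separate mouse, so p-values measure the spread between these libraries.

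The authors deposited a table of raw read counts for 55359 genes in 46 libraries and a second table of normalised values. Reads were aligned with STAR 2.7.9 to mm39, per the submitters' processing notes. The counting tool, the annotation and the strand setting of the counting are not given in the sources used here, so overlapping genes on opposite strands and near-identical copies can have shared reads. Per the file headers the second table holds deposited TPM, and its NEBNext columns are TPM with gene lengths that are not stated. Its 20 QuantSeq columns, although deposited under the same name, are deposited CPM: each equalled the count scaled by the total of its library within a tolerance of 0.01 (largest difference 4.66e-10), while 0 of 26 NEBNext columns did. In both tables each column was matched to a sample by its title, and 0 columns were left without a sample. The table lists 1597 gene names more than once under different identifiers, which were kept apart, and 0 entries name no gene.

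Libraries were grouped by genotype and time as the labels give them, and the replicate numbers used here follow the order of the samples and pair nothing. Total counts per library were 13356710 to 18397844 in F/F and 8477358 to 21014336 in wild type hearts of 1 week. They were 19024336 to 25856892 and 11390707 to 23529392 at 11 days, and 15955989 to 25650922 and 13824002 to 22070612 at 2 weeks. In QuantSeq they were 22099181 to 25199918 in F/+ and 22886964 to 33993289 in F/F hearts with cGas, and 23732239 to 27136038 and 25081489 to 28884658 without. Between 16821 and 23069 genes per NEBNext library and 19434 and 21575 per QuantSeq library had at least 1 count. Mitochondrially encoded mRNAs took 45.9 to 58.9% of QuantSeq counts. Among NEBNext libraries they took 22.3 ± 6.01% in F/F and 26.8 ± 3.01% in wild type hearts of 1 week, 4.87 ± 1.16% and 7.49 ± 2.14% at 11 days, and 14.8 ± 8.26% and 17.3 ± 4.13% at 2 weeks (SD). Y-linked genes and Xist matched the labelled sex in all 46 libraries. Of 93 pairs of replicates 0 were identical, and the lowest chi-square per degree of freedom between the counts of a pair was 9.70, so no library was counted as a repeat of another.

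Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr by group (minimum count 10, minimum total 15), estimateDisp, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 26 NEBNext libraries were fitted together (15627 genes) and so were the 20 QuantSeq libraries (14812 genes), so that all groups of a kit shared an estimate of the spread. Covariates were sex and, within 2 weeks, the sequencing pool (KIUC033 or KIUC035). Libraries of 1 week and of 11 days came from a pool each, so time and pool cannot be separated and no level is compared across times. Tested were Lmna F/F against wild type at each time, the differences between these effects, Lmna F/F against F/+ with and without cGas, the difference between those effects, and cGas null against wild type within each Lmna genotype. Normalised CPM use the TMM-scaled library size. Single genes were compared between groups with exact two-sided permutation tests of the mean. These tests, like those of list scores below, take no account of sex or pool. For genes with hardly any reads in a group, ratios of summed counts are given with 95% counting intervals, or against a floor of 3 counts summed over the group where no read was seen. Intervals and floors cover counting error only, since the libraries carry no molecular identifiers that were used here.

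A set of 39 gene lists (cell type markers, pathways and complexes of heart muscle) was tested per comparison with camera at an inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation beside it, and with fry. Fry tests whether the genes of a list move on balance one way, and does not compare them with other genes. Scores per library, the mean of log2(CPM + 1) over a list with a pseudocount of 1, were compared with exact permutation tests, a choice made after seeing the data. Named genes follow a rule. It takes Lmna and Cgas, then the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 log2 CPM, a symbol that is not a Gm number, Rik clone or accession, and no overlap of CPM between the groups. For differences of effects and for the cGas comparisons it takes 5 and 5, without the overlap condition. It adds up to 4 members of smallest p from each list that passed or had called members, and a panel of genes of cardiac stress, matrix, interferon response and nuclear envelope. The text prints part of the genes so named. Groups, tests, covariates, gene lists and this rule were fixed before the data were examined. Chromosomes were looked up by gene symbol in RefSeq genes of GRCm38.p6, an older assembly than the authors' mm39, and served only to ask which genes share a chromosome with Lmna or Cgas. Of these genes, 96.2% of the NEBNext and 94.8% of the QuantSeq genes were placed.

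Alternatives were RLE factors in place of TMM, no filter on low counts, fits without sex, without the pool term, within each pool, on males alone and on only the libraries compared, limma-voom (limma 3.58.1), limma-trend on log2(deposited TPM + 1) or log2(deposited CPM + 1), DESeq2 1.42.0, a 2-fold minimum, and each library left out in turn. DESeq2 was run without the filter on low counts, on every gene with a read in the libraries of the kit (31988 NEBNext and 29893 QuantSeq genes). Added after seeing the data were a covariate for the atrial marker score, a fit without the 11-day libraries and robust estimation of the prior. The same code was tested on simulated counts, drawn independently from the means, fitted dispersions and library sizes of these libraries, with 200 genes changed. The changed genes were drawn among those with a mean of at least 1 CPM, so recovery of weaker genes was not measured. Of 100 genes changed 2-fold and 100 changed 4-fold, it called 73 and 95 at 1 week, 37 and 91 at 11 days, 74 and 99 at 2 weeks, 78 and 99 in the QuantSeq comparison with cGas, and 57 and 100 in that without. It also called 15, 5, 8, 7 and 4 unchanged genes in the same order. Of the 39 lists it called 1 at 1 week, 1 for 11 days minus 1 week and 2 for cGas loss in F/+ hearts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.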

Results

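Messenger RNA of adult mouse hearts was measured in 46 libraries. Every mouse carried Myh6MCM, a Cre recombinase that is made in cardiomyocytes and becomes active on tamoxifen, and every mouse had received tamoxifen, so that the arms differed in their Lmna and cGas alleles. Lmna encodes lamins A and C of the nuclear lamina, and cGas (gene symbol Cgas) encodes an enzyme that senses DNA in the cytosol and signals through Sting1. The first set of libraries addresses when the heart's transcripts change after floxed Lmna is deleted, and the second whether that change depends on cGas. In the first set, 26 NEBNext poly(A) libraries covered 3 times after tamoxifen: 1 week (4 Lmna F/F and 5 Lmna +/+ hearts, here called wild type), 11 days (2 F/F and 3 wild type) and 2 weeks (5 F/F and 7 wild type). In the second set, 20 QuantSeq libraries, which count a tag at the 3' end of each transcript, covered 2 weeks: 6 Lmna F/+ and 6 F/F hearts with cGas, and 4 F/+ and 4 F/F hearts without it (cGas null). Total counts ran from 8477358 to 25856892 per NEBNext library and from 22099181 to 33993289 per QuantSeq library. Levels are given as normalised CPM (counts scaled to a common library total) with the SD between libraries, and differences as log2 fold changes ± SE from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05.

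Lmna was examined first, as a check on the labels. At 1 week it was lower in the F/F hearts, at 33.3 ± 4.38 CPM (n = 4) against 59.0 ± 9.22 in wild type (n = 5; exact two-sided permutation p = 0.0159). At 2 weeks it was 85.2 ± 26.9 CPM in F/F (n = 5) against 113 ± 7.02 in wild type (n = 7; exact permutation p = 0.0101). Of the 5 F/F libraries of 2 weeks, replicate 1 was at 42.2 CPM and 2 lay inside the wild type range, and on CPM without the TMM factors 4 of the 5 lay inside or above that range. At 11 days the 2 libraries labelled F/F were at 58.3 and 58.4 CPM and the 3 wild type libraries at 52.1, 106 and 118 (exact permutation p = 0.4, where 0.1 is the smallest p that 2 against 3 libraries can give). Lmna thus did not separate these arms, and they are called "labelled F/F" in what follows. In QuantSeq libraries Lmna was 20.5 ± 4.44 CPM in F/F and 22 ± 3.01 in F/+ hearts with cGas (n = 6 and 6, exact permutation p = 0.504). Without cGas it was 22.2 ± 5.87 and 23.7 ± 2.54 (n = 4 and 4, exact permutation p = 0.686). A 3' tag outside the deleted part of Lmna checks nothing about the deletion, and where that part lies is not given in the sources used here. Cgas tags were fewer in cGas null than in cGas wild type hearts, at 0.876 against 2.88 CPM among F/F hearts (n = 4 and 6, exact permutation p = 0.00952). Among F/+ hearts they were at 0.565 against 1.45 CPM (n = 4 and 6, exact permutation p = 0.0286). Cgas did not reach 0 in any group.

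**Figure D1:**
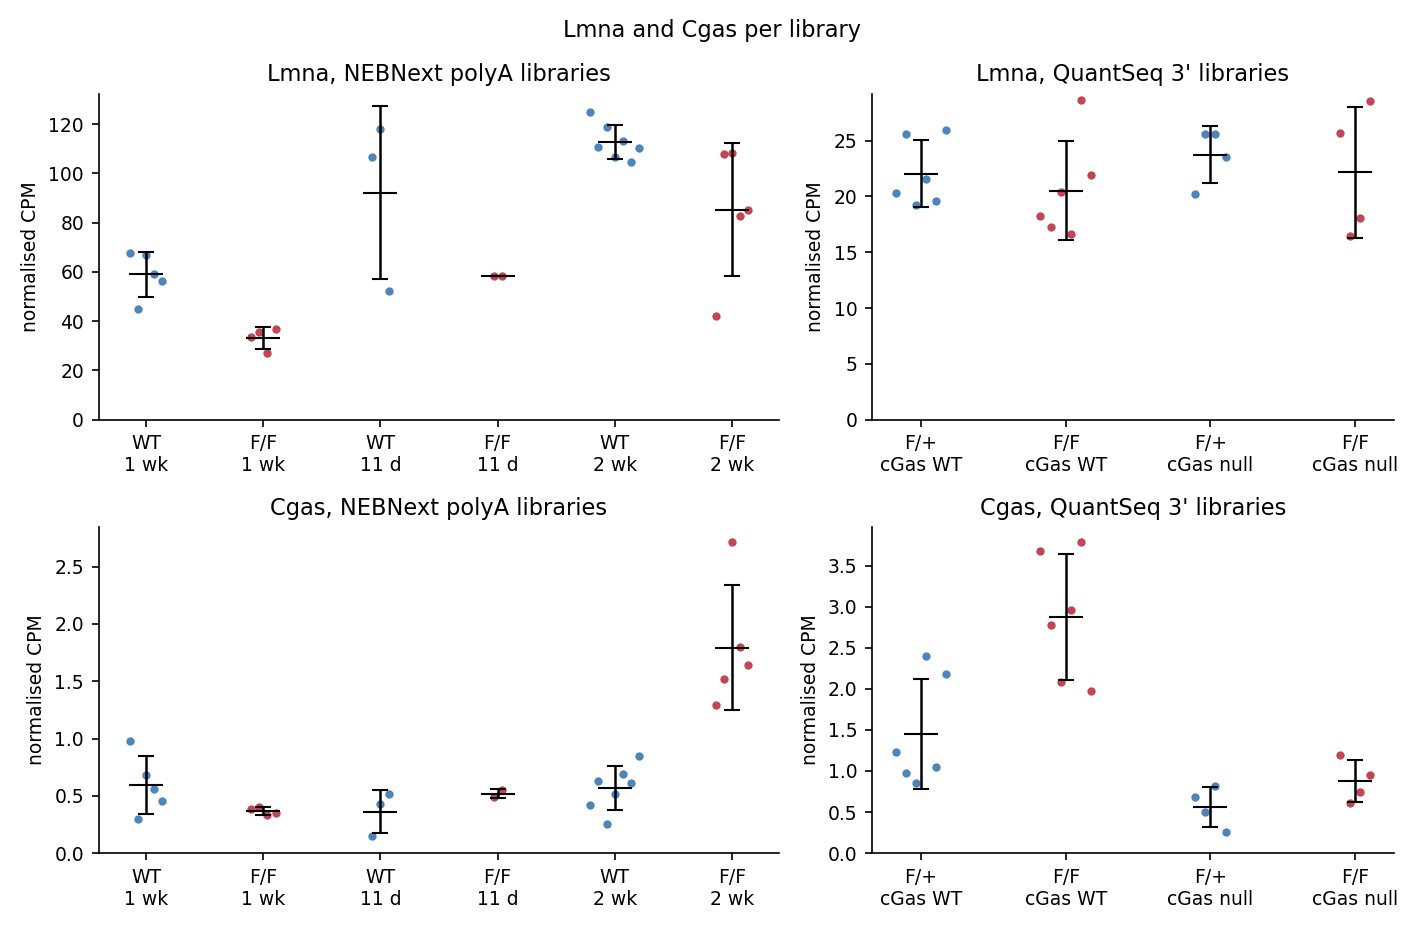
Normalised CPM (vertical axes, linear, from 0) of Lmna (top) and Cgas (bottom) in each NEBNext library (left) and QuantSeq library (right); points are libraries and bars the mean ± SD of a group. Lmna at 2 weeks averages 85.2 in F/F and 113 in wild type with 2 F/F libraries inside the wild type range, and Cgas averages 1.79 in F/F and 0.568 in wild type.

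At 1 week after tamoxifen, the first time sampled, F/F hearts differed from wild type at 4 of 15627 genes tested, 1 higher and 3 lower. H2af-ps2, a histone H2A pseudogene, was 412 times lower in F/F hearts (95% counting interval 114 to 3407, from 2 reads in 4 libraries against 913 in 5). Selenbp2, a selenium-binding protein gene, was 38.6 times lower (18.5 to 96.7, from 7 reads against 299). Ppm1j, a protein phosphatase gene, rose by 1.2 ± 0.16 on the log2 scale, from 6.30 ± 1.19 to 14.3 ± 1.41 CPM. The remaining gene, Gm42743, lies outside the rule for named genes and was chosen after its values were seen: it was 13.8 times lower (5.11 to 52.1, from 4 reads against 61). By the edgeR quasi-likelihood test the adjusted p was 2.03e-13 for H2af-ps2, 6.54e-08 for Selenbp2, 0.000537 for Ppm1j and 0.0363 for Gm42743. Lmna itself had a log2 fold change of -0.82 ± 0.22 (edgeR adjusted p = 0.315) and Cgas of -0.65 ± 0.41 (edgeR adjusted p = 0.603). H2af-ps2 belongs to a family of near-identical histone genes and Selenbp2 has a close copy in Selenbp1, so their reads can have been split between copies when the authors counted them. Selenbp2 and Ppm1j lie on chromosome 3, as Lmna does, and so do 5 of the 20 genes of smallest p at 1 week, where 0.965 are expected by chance. Of the 100 genes of smallest p, 7 lie there, where 4.82 are expected (Fisher's exact p = 0.341).

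No immune, matrix or contractile list passed at 1 week. The median log2 fold change was 0.02 for 25 macrophage markers, 0.23 for 26 inflammatory cytokines and chemokines, 0.11 for 36 interferon-stimulated genes, 0.25 for 37 structural matrix genes, and -0.08 for 22 sarcomere genes, which became 0.11 on deposited TPM (camera adjusted p = 0.951, 0.314, 0.275, 0.0899 and 0.983). By camera with an inter-gene correlation of 0.01, 5 of 39 lists passed. Endothelial markers (median 0.32), immediate early genes (0.31), feedback genes of MAPK signalling (0.27) and glycolysis (0.15) were higher, and the mitochondrially encoded mRNAs (-0.38) lower. None had a called member (0 in each), also when adjusted over the list alone. All 5 had an adjusted p = 0.99 with an estimated correlation, and 0 lists passed by fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. Unadjusted p was under 0.05 for 1539 genes (781 expected by chance), and the count of called genes was 3 to 9 when single libraries were left out, 9 without wild type replicate 1. The call of Gm42743 was lost without any 1 of F/F replicates 1 to 4 or wild type replicates 2, 3 and 4, and that of Ppm1j when only the libraries of 1 week were fitted. The count was 45 by DESeq2 and 109 by edgeR, both without the filter on low counts, and 2 when only the libraries of 1 week were fitted. On deposited TPM the calls were 2 higher and 3 lower, against 1 and 3, and the median of all genes was 0.10 against -0.0048. With that shift the medians were 0.57 for endothelial markers, 0.34 for immediate early genes, 0.21 for feedback genes of MAPK signalling, 0.31 for glycolysis and -0.26 for the mitochondrially encoded mRNAs.

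**Figure D2:**
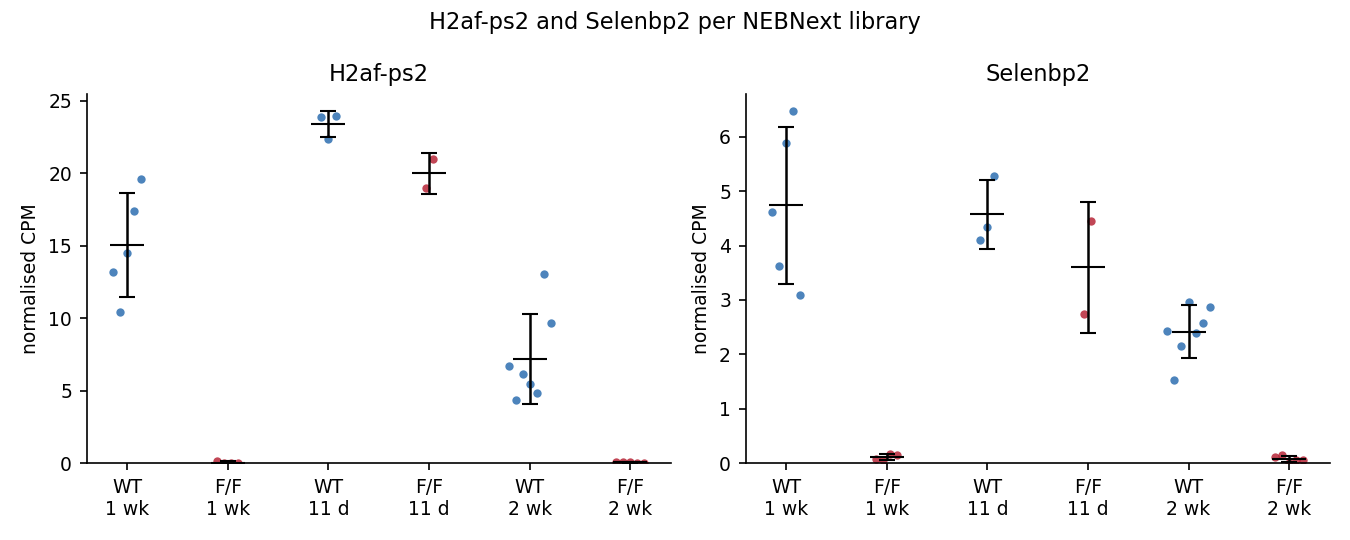
Normalised CPM (vertical axes, linear, from 0) of H2af-ps2 and Selenbp2 in each NEBNext library, with bars for the mean ± SD of a group. Both genes lie near 0 in every F/F library of 1 and 2 weeks and are present in the 2 libraries labelled F/F of 11 days. There H2af-ps2 is at 19.0 and 21.0 CPM, against 22.4 to 23.9 in wild type.

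At 11 days, edgeR called no gene between the 2 hearts labelled F/F and the 3 wild type hearts. H2af-ps2 and Selenbp2, near 0 in F/F hearts of the other times, were present in these libraries. H2af-ps2 was 1.15 times lower than in wild type (95% counting interval 1.05 to 1.27, from 808 reads against 1090) and Selenbp2 1.33 times lower (1.07 to 1.66, from 140 reads against 218). The edgeR quasi-likelihood test, limma-voom and limma-trend on deposited TPM each called 0 genes. Without the filter on low counts, DESeq2 called 46 and edgeR 201. Unadjusted p was under 0.05 for 1302 genes by edgeR (781 expected by chance) and 1167 by limma-voom, but for 723 by limma-trend on deposited TPM and 429 of 13765 when only the libraries of 11 days were fitted. It was so for 725 with the atrial marker score as a covariate, a choice made after seeing the data. Lmna had a log2 fold change of -0.67 ± 0.30 (edgeR adjusted p = 0.558) and Cgas of 0.46 ± 0.52 (edgeR adjusted p = 0.849). By camera, 5 of 39 lists were lower: 7 atrial markers (median -4.12, 4 members lower when adjusted over the list alone), 37 structural matrix genes (-0.46), 28 matricellular and TGF-beta genes (-0.50), 11 activated fibroblast genes (-1.05) and 7 mitochondrially encoded mRNAs (-0.51). Each of the 5 had an adjusted p = 0.963 with an estimated correlation, and fry passed 0 lists. On deposited TPM by limma-trend their medians were -1.86, -0.29, -0.31, -0.59 and -0.51 in the same order. Macrophage markers (median -0.05), inflammatory cytokines (-0.44) and interferon-stimulated genes (-0.25) did not pass (camera adjusted p = 0.848, 0.61 and 0.301). The count of 0 genes became 235 without wild type replicate 1 and 1 without labelled F/F replicate 2, wild type replicate 2 or wild type replicate 3. Leaving out an F/F library leaves a lone sample that is assumed to vary like the other groups. On CPM without the TMM factors, the atrial marker Sln ran from 0 to 128 over the NEBNext libraries and was over 10 in 8 of 26. At 11 days it was over 10 in 2 of 3 wild type and 0 of 2 labelled F/F libraries. The atrial marker Myl7 ran from 3.26 to 454 normalised CPM in wild type and from 5.78 to 6.94 in labelled F/F libraries. The lower atrial list thus came from high values in part of the wild type libraries. Whether the other lower lists share that source was not tested.

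At 2 weeks F/F hearts differed from wild type at 4562 of 15627 genes, 2537 higher and 2025 lower. Sprr1a, a gene induced in stressed cardiomyocytes, rose by 8.31 ± 0.80 on the log2 scale, and Spp1 (osteopontin) by 7.12 ± 0.73. Timp1, an inhibitor of matrix metalloproteinases, rose by 5.85 ± 0.55, Tnc (tenascin C) by 5.76 ± 0.59, and Il1rn, the interleukin 1 receptor antagonist, by 5.66 ± 0.69. Timp1 went from 4.65 ± 2.40 CPM in wild type (n = 7) to 341 ± 245 in F/F (n = 5), Spp1 from 0.848 ± 0.772 to 167 ± 142, and the acute phase gene Serpina3n from 11.3 ± 5.23 to 352 ± 204. Cthrc1, Serpina3n and Ptx3 rose by 5.30 ± 0.69, 5.22 ± 0.61 and 5.14 ± 0.50. By edgeR the adjusted p of these 8 genes lay between 4.12e-07 (Sprr1a, Timp1 and Ptx3) and 9.42e-06 (Cthrc1). Among the genes that fell, H2af-ps2 was 119 times lower (95% counting interval 57.5 to 296) and Selenbp2 30.2 times lower (15.7 to 66.6). Apln, the peptide hormone apelin, fell by 1.78 ± 0.27, Ky by 1.68 ± 0.31 and the skeletal muscle calcium channel Cacna1s by 1.65 ± 0.27 (edgeR adjusted p = 4.3e-05, 0.00033 and 8.82e-05). Esr1 also fell, by 1.75 ± 0.36 (edgeR adjusted p = 0.000909), but the Myh6MCM transgene contains parts of mouse Esr1, so reads of the gene and of the transgene cannot be told apart. Lmna had a log2 fold change of -0.46 ± 0.21 (edgeR adjusted p = 0.0983). Cgas rose by 1.48 ± 0.30 (edgeR adjusted p = 0.00075), from 0.568 ± 0.194 to 1.79 ± 0.549 CPM.

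**Figure D3:**
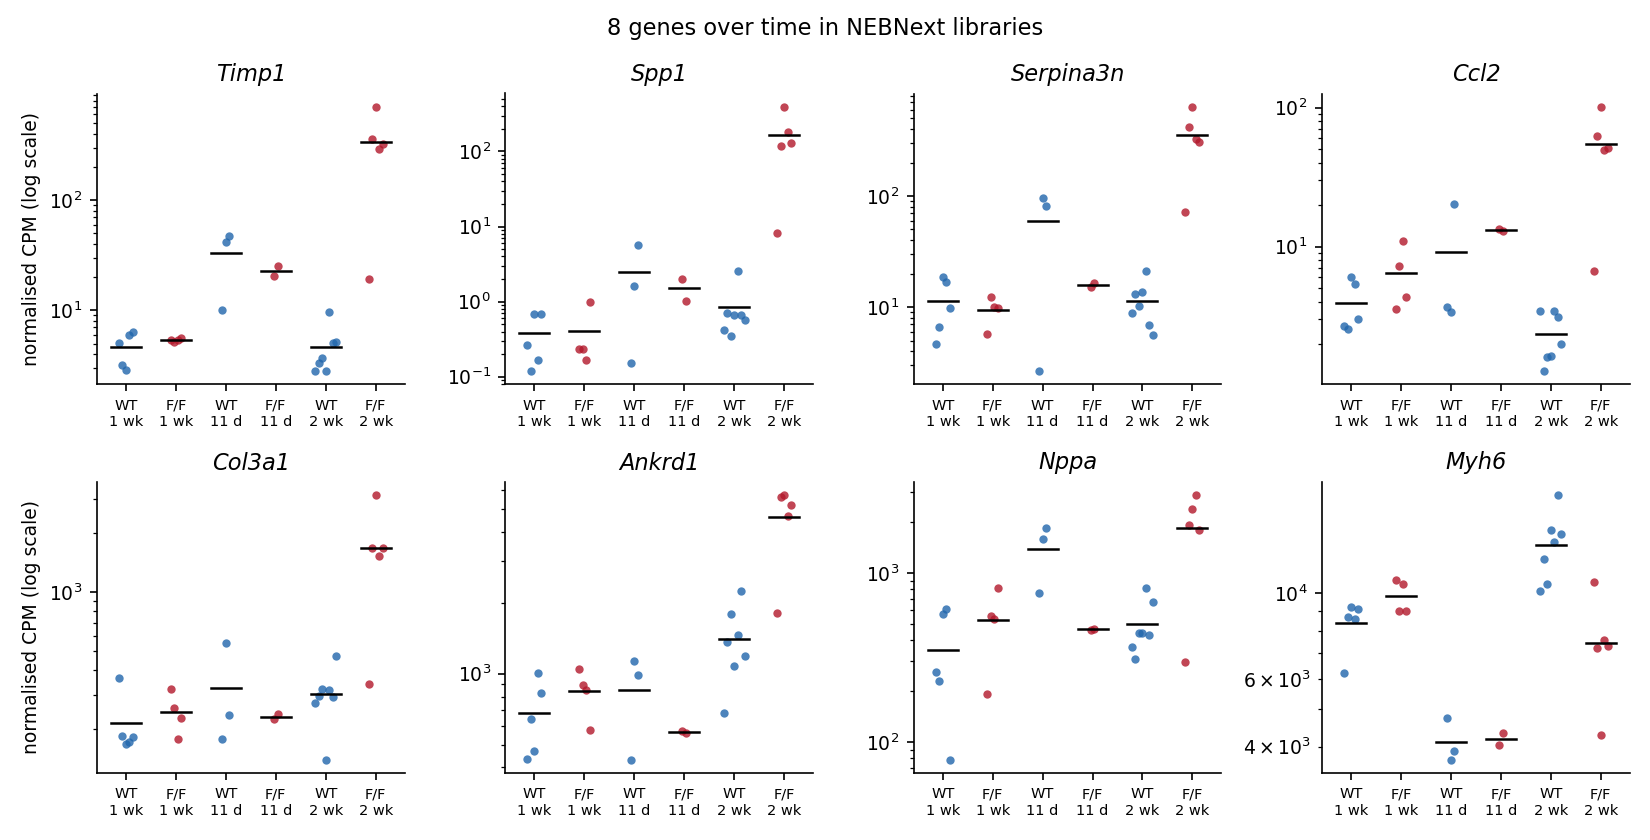
Normalised CPM (vertical axes, log scale) of 8 genes in each NEBNext library by genotype and time after tamoxifen; points are libraries and lines group means. At 2 weeks Timp1 averages 341 CPM in F/F and 4.65 in wild type, and Myh6 averages 7415 and 13355.

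Immune genes rose at 2 weeks. Of 25 macrophage markers 23 rose and 0 fell (24 and 0 when adjusted over the list alone; median log2 fold change 1.90). Among them were Lgals3, which rose by 4.42 ± 0.43, Ccr2, a chemokine receptor of monocytes, by 4.06 ± 0.42 and the protease gene Ctss by 2.72 ± 0.30. Inflammatory cytokines and chemokines rose at 23 of 26 members (23 when adjusted over the list alone; median 2.76), with Ccl2, which attracts monocytes, up by 4.42 ± 0.52 from 2.35 ± 0.931 to 54.4 ± 34 CPM and Ccl7 by 4.88 ± 0.49. Markers of T and NK cells rose at 11 of 16 members (13 when adjusted over the list alone; median 1.67), including Gzmb by 2.28 ± 0.46. The edgeR adjusted p of these 6 genes was between 4.12e-07 (Lgals3) and 0.000664 (Gzmb). By camera the 3 lists passed with adjusted p = 2.78e-24, 2.13e-17 and 3.16e-05, which became adjusted p = 0.132, 0.132 and 0.226 with an estimated correlation. On a score per library, the mean of log2(CPM + 1) over a list, macrophage markers were at 5.6 ± 0.707 in F/F and 3.81 ± 0.184 in wild type (n = 5 and 7, exact two-sided permutation p = 0.00126, adjusted p = 0.0041 over 39 lists). The difference was 1.21 among libraries of sequencing pool KIUC033 and 2.31 in pool KIUC035.

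Interferon-stimulated genes and genes of cytosolic DNA sensing were higher beside the macrophage markers. Of 36 interferon-stimulated genes 33 rose and 0 fell (35 when adjusted over the list alone; median 1.16). They include Ifi27l2a, which rose by 2.33 ± 0.36, Dhx58, a sensor of the RIG-I family, by 2.05 ± 0.30 and Ifit1 by 1.60 ± 0.28 (edgeR adjusted p = 5.5e-05, 3.14e-05 and 0.000161). In the DNA sensing list, which leaves out Cgas, 12 of 16 members rose (12 when adjusted over the list alone; median 1.26), including Zbp1, a sensor of Z-form nucleic acids, by 3.6 ± 0.52 and Sting1 by 1.65 ± 0.26 (edgeR adjusted p = 2.68e-05 and 7.07e-05). Camera adjusted p was 5.26e-17 for the interferon-stimulated and 1.64e-07 for the DNA sensing list, against adjusted p = 0.158 and 0.166 with an estimated correlation. The interferon-stimulated score was 4.33 ± 0.524 in F/F and 3.23 ± 0.171 in wild type (n = 5 and 7, exact permutation p = 0.00126). Of these libraries, F/F replicate 1 lay apart at 3.42, against 4.46 to 4.71 in the other 4 F/F libraries.

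Matrix and fibroblast activation genes rose as well. Of 37 structural matrix genes 24 rose and 0 fell (26 when adjusted over the list alone; median 1.09). Col3a1 rose by 2.11 ± 0.36, from 302 ± 97.8 to 1678 ± 993 CPM, and the collagen crosslinking enzyme gene Lox by 3.76 ± 0.46. Matricellular and TGF-beta genes rose at 20 of 28 members (22 when adjusted over the list alone; median 1.03). Matrix proteases and their inhibitors rose at 14 of 23 with 1 lower (16 and 1 when adjusted over the list alone; median 1.18). Activated fibroblast genes rose at 7 of 11 (9 when adjusted over the list alone; median 1.30), with Postn (periostin) up by 3.08 ± 0.47. The edgeR adjusted p was 0.000136 for Col3a1, 4.78e-06 for Lox and 5.16e-05 for Postn. These 4 lists passed by camera (adjusted p = 8.91e-10, 2.7e-10, 4.46e-06 and 0.000171) and had adjusted p = 0.278, 0.185, 0.222 and 0.226 with an estimated correlation. Markers of resting fibroblasts had a median of 0.29 with 4 of 16 members higher and 2 lower (camera adjusted p = 0.354). Proliferation genes rose at 26 of 28 members (27 when adjusted over the list alone; median 1.92, camera adjusted p = 1.46e-16, adjusted p = 0.132 with an estimated correlation). Top2a rose by 2.31 ± 0.33 and the mitotic kinesin gene Kif11 by 2.10 ± 0.30 (edgeR adjusted p = 2.25e-05 and 2.13e-05).

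Genes of contraction and energy metabolism fell as shares of the RNA of the heart, and levels within cardiomyocytes were not measured. Of 41 respiratory chain and TCA cycle genes 38 fell and 0 rose (39 when adjusted over the list alone; median -0.65), including Ndufs3 by 0.75 ± 0.13 and Idh3b by 0.80 ± 0.15. Of 26 fatty acid oxidation genes 19 fell (22 when adjusted over the list alone; median -0.70), including Hadha by 0.81 ± 0.16 and Acadvl by 0.87 ± 0.18. Sarcomere genes fell at 17 of 22 members (19 when adjusted over the list alone; median -0.63). Myh6, the main myosin heavy chain of the adult mouse ventricle, fell by 0.86 ± 0.18, from 13355 ± 2681 to 7415 ± 2279 CPM, Tnni3 by 0.94 ± 0.15 and Ckm by 1.03 ± 0.16. Calcium handling and ion channel genes fell at 11 of 27 members with 1 higher (14 and 1 when adjusted over the list alone; median -0.56), including Kcnip2 by 1.33 ± 0.23 and Jph2 by 1.04 ± 0.20. Glycolysis genes fell at 9 of 17 with 1 higher (9 and 1 when adjusted over the list alone; median -0.43), including the glucose transporter gene Slc2a4 by 1.04 ± 0.16. By edgeR the adjusted p of these 10 genes was between 4.09e-05 (Slc2a4) and 0.000983 (Myh6). Camera adjusted p for the 5 lists was 2.46e-18, 7.31e-11, 3.41e-12, 2.51e-05 and 0.00264, and with an estimated correlation the adjusted p = 0.163, 0.209, 0.132, 0.238 and 0.278. Genes of the fetal and stress program rose at 8 of 15 members with 1 lower (10 and 1 when adjusted over the list alone; median 0.95, camera adjusted p = 0.00413, adjusted p = 0.242 with an estimated correlation). Ankrd1 rose by 1.62 ± 0.30, from 1400 ± 504 to 4603 ± 1618 CPM, and Nppa by 1.64 ± 0.49, from 496 ± 181 to 1851 ± 967 CPM (edgeR adjusted p = 0.000345 and 0.0126). The call of Nppa was lost without F/F replicate 2.

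Other proteins of the nuclear envelope went both ways at 2 weeks. Of 24 genes in that list, which leaves out Lmna, 5 rose and 4 fell, and camera did not pass it (adjusted p = 0.945, test direction lower, median 0.09). Lmnb1, the gene of lamin B1, rose by 1.41 ± 0.25 and Tmem43 by 0.74 ± 0.15, while Tmem38a fell by 0.93 ± 0.17 and Tmem201 by 0.77 ± 0.15 (edgeR adjusted p = 0.000176, 0.000909, 0.00023 and 0.000552). Genes of ESCRT and envelope resealing did not pass (camera adjusted p = 0.877, test direction lower, median 0.01). Endothelial markers had a median of -0.24 with 4 of 14 lower (4 when adjusted over the list alone). Their camera adjusted p was 0.0223, and adjusted p = 0.466 with an estimated correlation. On deposited TPM their median was 0.04, where the median of all genes was 0.21 against 0.04 on counts.

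Over the 2-week comparison as a whole, fry passed 23 lists and camera 22, 16 higher and 6 lower, and 0 lists passed by camera with an estimated correlation. The count of genes was 3046 to 5261 when single libraries were left out, 349 in pool KIUC033 alone (2 F/F and 5 wild type) and 4894 in pool KIUC035 alone (3 and 2), and 1734 genes also differed by at least 2-fold. On deposited TPM the calls were 5253 higher and 705 lower with the median of all genes at 0.21, against 0.04 on counts. Of the called genes tested in a pool, 4210 of 4213 in KIUC033 and 4534 of 4534 in KIUC035 had the same sign as over both, with median log2 changes of 0.54 and 1.03 in that direction. These genes were called on the libraries of both pools together, so their agreement in sign was largely set by that choice. Timp1 rose by 3.76 and 6.43 in the 2 pools, Spp1 by 4.75 and 8.66 and Ccl2 by 2.81 and 4.83, called in each. The log2 fold changes of Col3a1 (1.24), Ankrd1 (1.12), Nppa (0.28), Myh6 (-0.43) and Cgas (1.37) in KIUC033 were not called there.

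**Figure D4:**
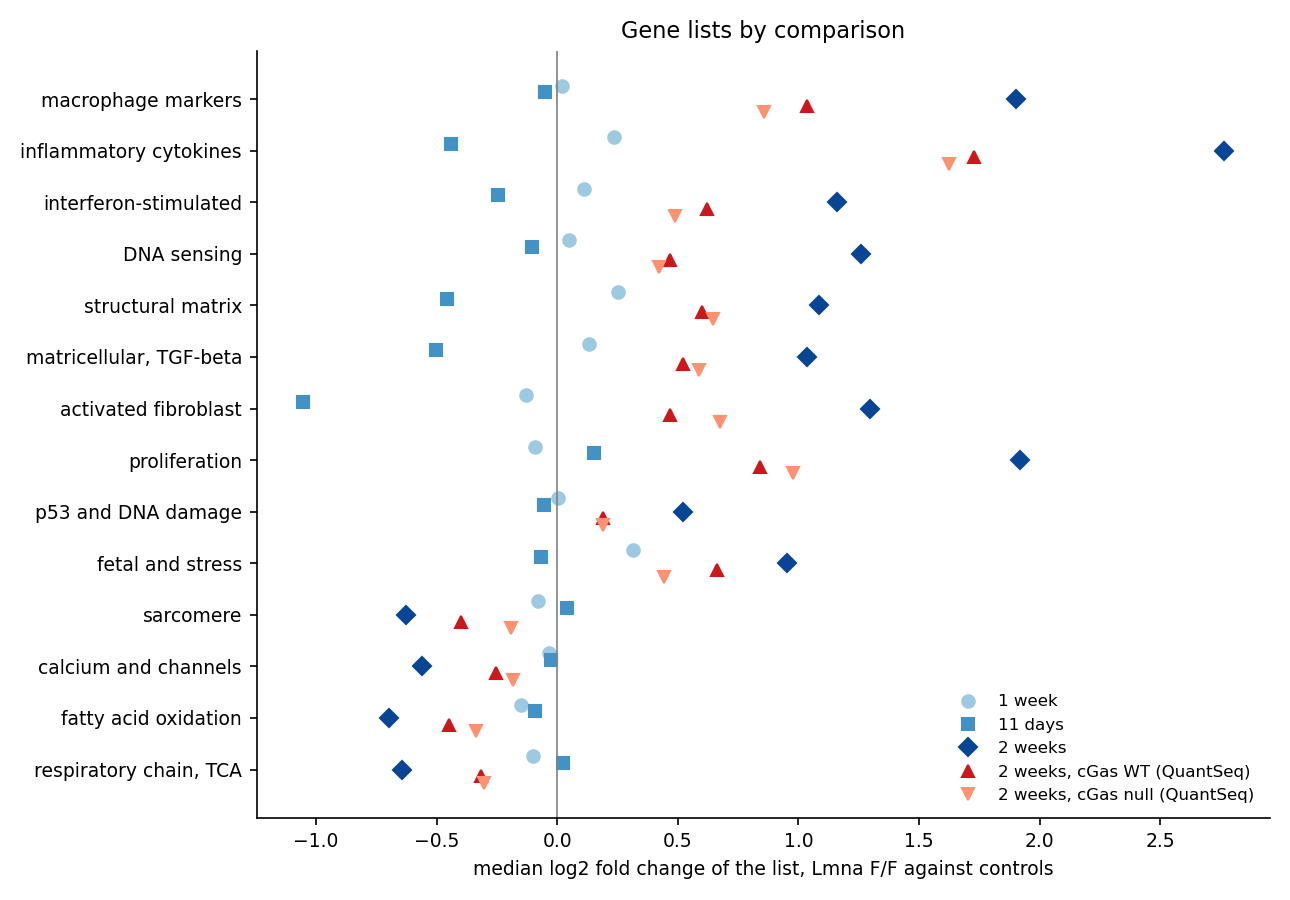
Median log2 fold change of 14 gene lists (horizontal axis), Lmna F/F against controls, at 1 week, 11 days and 2 weeks in NEBNext libraries and at 2 weeks with and without cGas in QuantSeq libraries. Macrophage markers have medians of 0.02, -0.05 and 1.90 over time and 1.03 and 0.86 with and without cGas.

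The Lmna effect differed between times when the differences themselves were tested. Each time had sequencing pools of its own, so a difference between times cannot be told apart from one between pools. Within 2 weeks, the called genes had a median change of 0.54 in pool KIUC033 and 1.03 in pool KIUC035. Between 2 weeks and 1 week it differed at 1938 genes by edgeR, 1019 with a higher and 919 with a lower effect at 2 weeks. The effect differed for Timp1 by 5.65 ± 0.82, Il1rn by 6.16 ± 1.22, Ccl2 by 3.73 ± 0.77, Postn by 2.98 ± 0.70, Cgas by 2.13 ± 0.51 and Myh6 by -1.10 ± 0.27 on the log2 scale (edgeR adjusted p = 0.0011, 0.00298, 0.00391, 0.00857, 0.00961 and 0.00995). Sez6l2 and Gnb3 had the most negative named differences, at -2.45 ± 0.46 and -2.33 ± 0.50 (edgeR adjusted p = 0.00225 and 0.00517), and Lmna did not differ (0.36 ± 0.30, edgeR adjusted p = 0.453). Macrophage markers (19 of 25 members), interferon-stimulated genes (14 of 36) and structural matrix genes (10 of 37) had a higher effect at 2 weeks, with medians of 1.94, 1.14 and 0.97, and respiratory chain genes (11 of 41) a lower one, at -0.57. Adjusted over the list alone these counts were 21, 23, 15 and 24. Camera passed 19 lists, 13 higher and 6 lower (adjusted p for those 4 = 6.29e-20, 5.05e-11, 1.1e-05 and 3.99e-11, and adjusted p = 0.231, 0.305, 0.507 and 0.305 with an estimated correlation). The count was 1235 and 1209 without F/F replicates 1 and 3 of 1 week, 2966, 1130 and 1278 without F/F replicates 1, 2 and 3 of 2 weeks, and 1133 without wild type replicate 6 of 2 weeks. The call of Postn was lost without F/F replicate 2 of 2 weeks. A difference of at least 2-fold was called for 1055 genes. On deposited TPM the split was 1535 higher and 586 lower, with the median of all genes at 0.11 against 0.04.

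Between 11 days and 1 week the effect differed at 2 genes, H2af-ps2 (8.44 ± 0.52) and Selenbp2 (4.94 ± 0.61; edgeR adjusted p = 1.47e-10 and 0.000158), both higher at 11 days, and the call of Selenbp2 was lost on deposited TPM, which left 1 gene. The count was 16 by DESeq2 and 117 by edgeR, both without the filter on low counts. Camera passed 6 lists, structural matrix (median -0.68), matricellular, immediate early, atrial and interferon-stimulated genes with a lower and respiratory chain genes with a higher effect at 11 days (adjusted p between 0.000121 and 0.0429, and adjusted p = 0.929 for each with an estimated correlation). The count became 13 without wild type replicate 1 of 11 days. Between 2 weeks and 11 days the effect differed at 1832 genes, 1213 higher and 619 lower at 2 weeks, including Spp1 by 7.83 ± 1.32 and Timp1 by 6.40 ± 1.00 (edgeR adjusted p = 0.002 and 0.00175). That count was 2773 and 943 without F/F replicates 1 and 2 of 2 weeks, 1045 without wild type replicate 6 of 2 weeks. It was 607 and 337 without labelled F/F replicates 1 and 2 of 11 days, and 3172, 732 and 1063 without wild type replicates 1, 2 and 3 of 11 days. With the atrial marker score as a covariate, a choice made after seeing the data, it was 1028. Camera passed 20 lists, 14 higher and 6 lower, of which 0 passed with an estimated correlation. On deposited TPM the split of genes was 1916 higher and 248 lower, with the median of all genes at 0.26 against 0.11.

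In QuantSeq libraries with cGas, F/F hearts differed at 2 weeks from F/+ hearts at 686 of 14812 genes, 554 higher and 132 lower (edgeR quasi-likelihood test). Spp1 rose by 4.59 ± 0.55 on the log2 scale, from 0.291 ± 0.279 to 11.2 ± 10.5 CPM (n = 6 and 6). Serpina3n rose by 3.64 ± 0.49, Timp1 by 3.62 ± 0.57, from 3.49 ± 3.29 to 62.4 ± 50.7 CPM, and Ccl2 by 3.40 ± 0.35, from 2.18 ± 0.644 to 27.8 ± 13.1 CPM. Ankrd1 rose by 1.5 ± 0.27, from 1329 ± 569 to 4554 ± 2717 CPM. Nmrk2, a nicotinamide riboside kinase gene induced in stressed heart muscle, rose by 2.37 ± 0.41, Gdf15 by 2.12 ± 0.34 and Cdkn1a, the gene of the cell cycle inhibitor p21, by 1.57 ± 0.31. Dixdc1 and Apln fell by 1.11 ± 0.20 and 1.16 ± 0.24. The edgeR adjusted p of these 10 genes was between 1.73e-05 (Ccl2) and 0.00586 (Apln). Lmna (-0.13 ± 0.16), Cgas (0.91 ± 0.29) and Myh6 (-0.59 ± 0.18) were not called (edgeR adjusted p = 0.7, 0.0727 and 0.0685).

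With cGas present, 20 of 25 macrophage markers rose (23 when adjusted over the list alone; median 1.03), among them Gpnmb by 3.08 ± 0.45 and Lgals3 by 2.49 ± 0.40. So did 13 of 24 inflammatory cytokines (21 when adjusted over the list alone; median 1.73), among them Ccl7 by 2.87 ± 0.33. Proliferation genes rose at 15 of 28 members (24 when adjusted over the list alone; median 0.84), matricellular genes at 8 of 28 (14; median 0.52) with Tnc up by 3.23 ± 0.59. Structural matrix genes rose at 4 of 37 (11; median 0.60) and matrix proteases and inhibitors at 5 of 23 (11; median 0.58) with Mmp12 up by 2.96 ± 0.35. The edgeR adjusted p of these 5 genes was between 4.72e-05 (Ccl7 and Mmp12) and 0.00315 (Tnc). Of 36 interferon-stimulated genes edgeR called 2 higher (19 when adjusted over the list alone, median 0.62), DESeq2 8 and limma-trend on deposited CPM 9. Those called by edgeR were Ifi27l2a by 1.34 ± 0.33 and Lgals3bp by 0.82 ± 0.24 (edgeR adjusted p = 0.0207 and 0.0464). Ifit1 was at 1.22 ± 0.36 (edgeR adjusted p = 0.053). In the DNA sensing list 4 of 15 rose (6 when adjusted over the list alone; median 0.47), Sting1 by 0.90 ± 0.18 (edgeR adjusted p = 0.00511). Fatty acid oxidation (median -0.45), sarcomere (-0.40) and respiratory chain genes (-0.32) were lower as lists with 0 members called by edgeR, and 16, 0 and 0 lower when adjusted over the list alone. DESeq2 called 6, 2 and 6 of their members lower. On deposited CPM by limma-trend their medians were -0.31, -0.23 and -0.17. These 3 lists did not pass with an estimated correlation (adjusted p = 0.158, 0.179 and 0.234). Atrial and adipocyte markers had medians of 2.15 and 1.61 with 0 members called and did not pass (camera adjusted p = 0.599 and 0.191). Camera passed 20 lists, 16 higher and 4 lower, and fry 17. With an estimated correlation 3 lists passed: macrophage (adjusted p = 0.0348), inflammatory cytokines (adjusted p = 0.0176) and p53 targets and DNA damage (adjusted p = 0.018). The other lists named here that passed by camera had adjusted p between 0.0746 and 0.244 with an estimated correlation. By exact permutation of scores per library, macrophage markers (4.61 ± 0.457 against 3.54 ± 0.162, n = 6 and 6, exact p = 0.00216, adjusted p = 0.0141) passed. Interferon-stimulated genes (3.31 ± 0.369 against 2.82 ± 0.207, n = 6 and 6, exact p = 0.0281, adjusted p = 0.061) did not. The count of 686 genes became 190 and 201 without F/+ replicates 1 and 3, and 387, 427, 1169 and 347 without F/F replicates 1, 2, 4 and 5. The call of Ifi27l2a was lost without F/+ replicate 1 or 3 or F/F replicate 1 or 3, and that of Lgals3bp without any 1 of F/+ replicates 1, 3, 4 and 5 and F/F replicates 1, 2, 3, 5 and 6. The count was 1183 without the filter on low counts and 345 with a 2-fold minimum. On deposited CPM by limma-trend the split was 678 higher and 26 lower, with the median of all genes at 0.10 against -0.01.

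The Lmna effect at 2 weeks was compared between the kits, which share no libraries but differ in their control genotype. Over 13657 genes tested in both, the log2 fold changes had a Pearson correlation of 0.774 and a Spearman correlation of 0.747 across genes, which are not independent replicates, and 78.2% had the same sign. Of the genes called in both, 607, all had the same sign: 507 were higher, where independent lists would share 88.2, and 100 lower, where they would share 18.3. Genes called in both include Timp1, Spp1, Ccl2, Serpina3n, Lgals3, Ankrd1 and Sting1 among the higher and Apln among the lower.

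Without cGas, F/F hearts differed from F/+ hearts at 78 of 14812 genes, 74 higher and 4 lower (edgeR quasi-likelihood test). All 4 F/+ hearts were from males and 2 of the 4 F/F hearts from females, so sex in the F/+ arm was fitted only through other groups. The genes with the highest named changes included those seen with cGas. Spp1 rose by 4.45 ± 0.68, from 0.240 ± 0.107 to 3.72 ± 2.94 CPM (n = 4 and 4), Tnc by 4.59 ± 0.78 and Il1rn by 4.38 ± 0.69. Timp1 rose by 4.15 ± 0.69, from 2.55 ± 0.497 to 37.3 ± 33.6 CPM, and Ccl2 by 3.18 ± 0.42, from 1.59 ± 0.477 to 12.6 ± 9.35 CPM. Ccl7 rose by 2.83 ± 0.41, Ccr2 by 2.61 ± 0.51, Lgals3 by 2.50 ± 0.49, Nmrk2 by 2.41 ± 0.51 and the replication gene Mcm6 by 1.10 ± 0.22, and Apln fell by 1.33 ± 0.30 and Nmnat3 by 0.75 ± 0.17. By edgeR the adjusted p of these 12 genes was between 0.00213 (Ccl2) and 0.0498 (Nmnat3). The other lower genes, Olfr1396 (-1.91) and A530016L24Rik (-1.16), were chosen after their values were seen. Lmna (-0.04 ± 0.19) and Cgas (0.74 ± 0.40) were not called (edgeR adjusted p = 0.97 and 0.571).

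As lists, inflammatory cytokines (5 of 24 members higher, 16 when adjusted over the list alone; median 1.62), macrophage markers (4 of 25, 19; median 0.86), proliferation genes (2 of 28, 22; median 0.98) and structural matrix genes (0 of 37, 12; median 0.64) were higher in F/F hearts without cGas. Of these 4 only inflammatory cytokines passed with an estimated correlation, where the other 3 had adjusted p = 0.0786, 0.078 and 0.289. Interferon-stimulated genes were higher as a list with 0 of 36 members called by edgeR (2 when adjusted over the list alone, median 0.49, camera adjusted p = 1.44e-08, adjusted p = 0.328 with an estimated correlation). DESeq2 called 1 interferon-stimulated and 1 structural matrix gene higher. Respiratory chain (median -0.30), fatty acid oxidation (-0.33) and sarcomere genes (-0.19) were lower, with adjusted p = 0.329, 0.283 and 0.458 with an estimated correlation. On deposited CPM by limma-trend their medians were -0.11, -0.16 and -0.04, with the median of all genes at 0.11 against -0.02. Atrial and adipocyte markers had medians of -0.56 and -0.27 and did not pass (camera adjusted p = 0.157 and 0.639). Camera passed 22 lists, 17 higher and 5 lower, and fry 6, and with an estimated correlation 2 passed, inflammatory cytokines (adjusted p = 0.04) and p53 targets (adjusted p = 0.0113). Scores per library passed for 0 lists after adjustment (4 against 4 libraries can give no exact p below 0.0286), and the interferon-stimulated score was 2.92 ± 0.0728 against 2.53 ± 0.298 (n = 4 and 4, exact permutation p = 0.0857). The 78 genes became 10 by limma-voom and 13 by limma-trend on deposited CPM, and without the filter on low counts 227 by DESeq2 and 515 by edgeR. In edgeR they became 21 without sex, 171 among males alone, 246 when only these libraries were fitted and 172 with the atrial marker score as a covariate, a choice made after seeing the data. The count of 78 genes became 11, 39, 175 and 8 without F/F replicates 1, 2, 3 and 4, and 18, 7 and 12 without F/+ replicates 2, 3 and 4. Ccl2, Ccl7, Spp1 and Il1rn kept their calls in all 8 of these fits, while Timp1 and Tnc lost theirs without F/F replicate 4 or F/+ replicate 3. Without F/F replicate 1 or 4, or F/+ replicate 2, 3 or 4, the calls of Ccr2, Lgals3, Nmrk2, Mcm6, Apln and Nmnat3 were lost. Those of Nmrk2, Apln and Nmnat3 were also lost without F/F replicate 2, of Apln and Nmnat3 without F/F replicate 3 and of Nmnat3 without F/+ replicate 1.

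**Figure D5:**
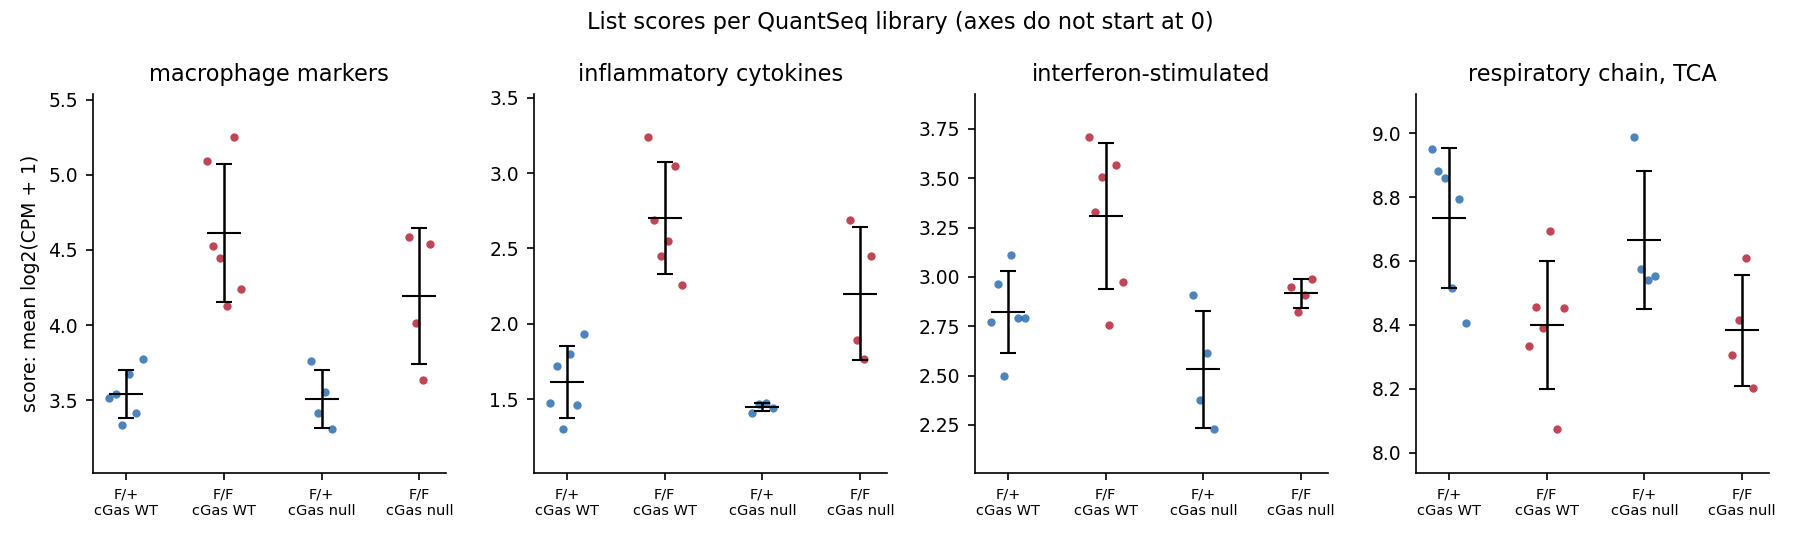
Score per QuantSeq library (vertical axes, mean of log2(CPM + 1) over a list, not starting at 0) for 4 gene lists in the 4 genotypes, with bars for the mean ± SD. The interferon-stimulated score averages 2.82 and 3.31 in F/+ and F/F hearts with cGas and 2.53 and 2.92 without.

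Whether the Lmna effect depended on cGas was tested as an interaction, and 0 of 14812 genes passed. The F/+ cGas null arm held males alone, so sex was fitted there only through the other groups. The edgeR quasi-likelihood test, limma-voom, limma-trend on deposited CPM and DESeq2 each called 0 genes and edgeR without the filter on low counts 23, unadjusted p was under 0.05 for 215 genes where chance gives 741, and the count stayed 0 in each of the 20 fits without a library. Tnc, for example, had a difference between effects of 1.36 ± 1.03 (edgeR adjusted p = 1). Of 39 lists 0 passed by camera or fry, and the differences between effects had medians of -0.17 for macrophage markers, -0.16 for interferon-stimulated genes, -0.05 for inflammatory cytokines and 0.02 for structural matrix genes, which became -0.02 on deposited CPM (camera adjusted p = 0.061, 0.51, 0.69 and 0.961). These differences had medians of -2.54 for atrial and -1.98 for adipocyte markers (camera adjusted p = 0.061 and 0.0611). On simulated counts with these libraries, the interaction was called for 92 of 100 genes changed 4-fold and 20 of 100 changed 2-fold, so differences of 2-fold were mostly below what the test could call. The simulation drew counts independently, without the structure that other splits of these libraries show. The SE of the difference was 1.03 for Tnc, 1.00 for Spp1 and 0.88 for Timp1, so even 4-fold differences of such genes could be missed. Of the 686 genes called with cGas, 672 had the same sign without it, with a median change of 0.81 against 1.00 on the log2 scale, and 34 had an unadjusted interaction p under 0.05. Since these genes were chosen by their calls with cGas, their change with cGas is inflated by that choice, and the smaller median without it does not by itself show a dependence on cGas. The 2 comparisons share no libraries, and 71 genes were called in both, each with the same sign (67 higher, where independent lists would share 2.77, and 4 lower, where they would share 0.0356).

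Loss of cGas was compared within each Lmna genotype, and no single gene passed in either. In F/F hearts the edgeR quasi-likelihood test, limma-voom and limma-trend on deposited CPM called 0 genes and DESeq2 3, with unadjusted p under 0.05 for 850 genes. In F/+ hearts the same tools called 0, 0, 0 and 3, with 616 genes at unadjusted p under 0.05. Without the filter on low counts edgeR called 93 in each. It called 2 in F/F hearts when only these libraries were fitted and 1 in F/+ hearts among males alone. Cgas had log2 fold changes of -1.71 ± 0.33 and -1.54 ± 0.40 in F/F and F/+ hearts (edgeR adjusted p = 0.26 and 0.993). Isg15 had -0.97 ± 0.34 and -0.74 ± 0.38, and Myh11, a smooth muscle myosin gene, 1.23 ± 0.36 and 1.17 ± 0.41 (edgeR adjusted p = 0.85 and 0.993 for both). Of the 20 genes of smallest p in F/F hearts, 7 lie on chromosome 9 with Cgas, and 4 of the 20 in F/+ hearts, where 1.14 are expected by chance. By Fisher's exact test the adjusted p was 0.0012 in F/F and 0.0553 in F/+ hearts. In F/F hearts Ccl2 (-1.27 ± 0.35), Ifit1 (-1.25 ± 0.40) and Irf7 (-0.87 ± 0.31) were also below 0 (edgeR adjusted p = 0.85). Interferon-stimulated genes were lower as a list in both genotypes. A total of 36 of 36 members had a negative fold change in F/F hearts (median -0.47, camera adjusted p = 1.61e-14) and 35 of 36 in F/+ hearts (median -0.33, camera adjusted p = 1.11e-07). The lists had 0 members called, also when adjusted over the list alone. These became adjusted p = 0.299 and 0.718 with an estimated correlation. The scores per library did not pass, at 2.92 ± 0.0728 in null against 3.31 ± 0.369 in F/F hearts (n = 4 and 6, exact permutation p = 0.0952) and 2.53 ± 0.298 against 2.82 ± 0.207 in F/+ hearts (n = 4 and 6, exact permutation p = 0.1).

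Macrophage markers were lower beside them, with medians of -0.49 and -0.30 in F/F and F/+ hearts (camera adjusted p = 2.53e-12 and 0.00315). So were inflammatory cytokines (-0.71 and -0.86) and DNA sensing genes (-0.31 and -0.29), while endothelial (0.33 and 0.32) and mural markers (0.27 and 0.25) were higher. Each of these lists had an adjusted p of 0.299 in F/F and of 0.718 or 0.82 in F/+ hearts with an estimated correlation. On deposited CPM by limma-trend the medians of inflammatory cytokines were -0.37 in F/F and -0.35 in F/+ hearts. In all, camera passed 11 lists in F/F hearts (3 higher and 8 lower) and 9 in F/+ hearts (4 higher and 5 lower), and fry 0 in both. All 4 F/+ cGas null hearts were from males, so sex could be fitted there only through the other groups. Atrial markers were higher in the F/+ null hearts (median 1.81, camera adjusted p = 0.000326, adjusted p = 0.718 with an estimated correlation).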

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

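Of the tests reported in this part, the counts over other splits of the libraries, the count of genes on the chromosome of Lmna, the levels of H2af-ps2 in wild type libraries and the comparison of flanking genes at 11 days were chosen only after the result was seen.

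In 144 groups of 4 to 7 libraries (sample measures, list scores and single genes), 14 had a library whose gap to the others exceeded Dixon's 95% critical value, where chance alone gives about 7.2. The group of F/F hearts with cGas had 1 library, replicate 4, with 33993289 total counts against 22886964 to 27003861 in the others. F/F replicate 1 of 2 weeks stood apart in the interferon-stimulated score, at 3.42 against 4.46 to 4.71, and in Ankrd1, at 1805 against 4671 to 5721 CPM. Wild type replicate 5 of 2 weeks had Timp1 at 9.65 against 2.81 to 5.11 CPM and Spp1 at 2.57 against 0.351 to 0.697 CPM. Wild type replicate 1 of 1 week had a sarcomere score of 11.5 against 11.7 in each of the others, Col3a1 at 367 against 168 to 185 CPM and Myh6 at 6196 against 8593 to 9216 CPM. The F/+ heart with cGas numbered 6 had Timp1 at 10.1 against 1.28 to 2.86 CPM, Spp1 at 0.857 against 0.126 to 0.213 CPM and Col3a1 at 438 against 101 to 182 CPM. F/F replicate 4 of 1 week had Spp1 at 0.991 against 0.166 to 0.232 CPM. F/F cGas null replicate 3 had Nppa at 2195 against 148 to 430 CPM, and F/+ cGas null replicate 1 had a respiratory chain score of 8.99 against 8.54 to 8.58.

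Differences of the Lmna effect between times were tested as differences in edgeR: 1938 genes between 2 weeks and 1 week (1019 higher and 919 lower at 2 weeks), 2 between 11 days and 1 week (2 and 0), and 1832 between 2 weeks and 11 days (1213 and 619). Time and sequencing pool came together here and cannot be told apart.

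The first pattern weighed is that genes of small p at 1 week lie on the chromosome of Lmna. Among the 20 genes of smallest p, 5 (Selenbp2, Ppm1j, Tmem144, Setdb1 and Mme) lie on chromosome 3, where 0.965 are expected (Fisher's exact p = 0.00218, adjusted p = 0.00872 over all such counts), but the 100 of smallest p hold 7 against 4.82 (Fisher's exact p = 0.341) and the 20 of 2 weeks hold 5 as well, among them Sprr1a, Ptx3 and Ctss, so this count does not single out inherited alleles. Strain variants inherited with the Lmna alleles may account for part of these genes, but the values do not decide it. Of chromosome 3 genes with p under 0.01 at 1 week, 12 of 20 (60%) kept their sign in the separate 2-week libraries, near an even share. Elsewhere 124 of 365 (34%) did (one-sided Fisher's exact p = 0.0184). That p rests largely on the genes elsewhere, most of which changed sign (median 2-week change in the 1-week direction -0.15). It also treats genes of the same libraries as independent. On chromosome 3 the median change in the 1-week direction went from 0.74 to 0.10. Ppm1j was at 11.2 ± 0.534 CPM in F/F (n = 5) against 12.2 ± 1.91 in wild type (n = 7) at 2 weeks. An early response to loss of lamins A and C stays open for these genes, since deletion and inherited alleles always come together in the time course and the explanations cannot be told apart there. No wild type library of 1 or 2 weeks shared the loss of H2af-ps2 (lowest 4.30 CPM, without the TMM factors), but this gene lies on chromosome 13, and QuantSeq hearts of 2 weeks held it at 0.934 ± 0.274 in F/F against 1.10 ± 0.281 CPM in F/+ with cGas (n = 6 and 6) and at 0.992 ± 0.441 against 1.53 ± 0.744 without (n = 4 and 4), so no such loss appeared in the F/F hearts of that set.

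The second pattern is the 0 genes called at 11 days, with H2af-ps2 and Selenbp2 near wild type level (1.15 and 1.33 times lower) in the libraries labelled F/F. An effect like that of 2 weeks, hidden by the few libraries, did not show but is not excluded. Genes 2-fold higher at 2 weeks minus those 2-fold lower had a median difference of -0.14 at 11 days (log2 CPM, -0.137). The other splits of these 5 libraries reached 0.490. The difference cannot decide on a hidden effect, because the arms also differed in the atrial marker Sln. Without the TMM factors, Sln was over 10 CPM in 2 of 3 wild type and 0 of 2 labelled F/F libraries. Whether that lowered the difference was not tested, and without wild type replicate 1 edgeR called 235 genes. An exchange of labels within the 11-day libraries is argued against, since no wild type library lacked H2af-ps2 (lowest 18.0 CPM, without the TMM factors). This holds as far as F/F mice of 11 days would lack it like those of the other times. Mice without the chromosome 3 segment of the other F/F mice, wrongly labelled ones included, remain a candidate explanation that cannot be told apart from the rest: both libraries lay nearer the wild type mean at 3 of 6 chromosome 3 genes (Strit1, Selenbp2 and Setdb1) and nearer the F/F mean at 2 (Mtfr1 and Tmem144). Selenbp2 belongs to the pattern that prompted this count and adds nothing to it. H2af-ps2 lies on chromosome 13, so a missing chromosome 3 segment alone would not account for it. A true absence of an effect was not tested beyond these values, and Esr1, picked out after its values were seen, was lower in both libraries labelled F/F (2087 and 2404 CPM) than in any wild type library (lowest 4040), the direction it had at 2 weeks, without being called (-0.94 ± 0.54 on the log2 scale, edgeR adjusted p = 0.662).

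The third pattern is the lower interferon-stimulated list in cGas null hearts of both Lmna genotypes. Fewer macrophages may contribute: with the macrophage score of each library as a covariate the median in F/F hearts went from -0.47 to -0.09 (-0.0944, camera adjusted p = 0.145) and in F/+ hearts from -0.33 to -0.15 (camera adjusted p = 0.0255), but the covariate can also remove a true effect of cGas on macrophages. Sex stays open, because among males alone the median was -0.44 in F/F (camera adjusted p = 5.22e-06) and -0.08 in F/+ hearts (camera adjusted p = 0.109). Variants inherited with the cGas null allele could not be examined through the list, of which 0 of 36 members lie on chromosome 9 with Cgas (highest camera adjusted p = 1.11e-07 with or without such members), although 7 of the 20 genes of smallest p in F/F hearts lie there against 1.14 expected (Fisher's exact p = 7.51e-05, adjusted p = 0.0012). Chance was not excluded, with the list as low in 6 of 100 splits of the F/F and 7 of 100 of the F/+ libraries (-log10 camera adjusted p of 13.8 and 6.95, highest of the other splits 20.5 and 17.7), and a direct effect of cGas is open as well.

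Other splits of the same libraries into groups of the same sizes were fitted with the same covariates, except that the pool term cannot be estimated in the split along the pools and was left out there. Chance was excluded for the genes called at 2 weeks (4562, as many in 1 of 60 splits, highest other 2507). By the share of splits alone it was also excluded for F/F against F/+ with cGas (686, 2 of 100, highest other 1683). It was not excluded for the genes at 1 week (4, as many in 3 of 60 splits, highest other 13) or for F/F against F/+ without cGas (78, 2 of 35, highest other 261). At 2 weeks the split that called 2507 genes was that of pool KIUC035 against pool KIUC033, which is a structure of the libraries and was fitted without the pool term. Without that term the real split called 4835, and the counts within the pools were 349 and 4894. With cGas, the split that called 1683 exchanged F/+ replicate 6 and F/F replicate 4 and otherwise followed the labels. The real count was 934 without that F/+ library and 1169 without that F/F library. Without cGas the split that called 261 exchanged F/+ replicate 1 and F/F replicate 4 and otherwise followed the labels. The libraries thus hold a structure that departs from the labels at these hearts. Whether any labels were exchanged was not tested. Genes at unadjusted p under 0.05 were as many in 88 of 100 splits for the interaction (215, highest other 2851), in 37 of 100 for cGas loss in F/F hearts (850, highest other 2699) and in 42 of 100 in F/+ hearts (616, highest other 2941), so chance was not excluded. For cGas loss the highest are several times the real count, which points to a structure of the samples. For the interaction, the splits exchanged Lmna labels within each cGas genotype. Such a split can turn the Lmna effect itself into a difference between effects. Its counts of genes and lists thus cannot test chance for the interaction. Lmna labels were likewise exchanged within each time for 2 weeks minus 1 week (1938 genes, as many in 1 of 60 splits, highest other 0). Those counts of genes and lists cannot test chance for that difference either.

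Counts of lists past camera's threshold were as large in 45 of 60 splits at 1 week (5, highest other 17), 22 of 60 at 2 weeks (22, highest other 26), and 15 of 60 for 2 weeks minus 1 week (19, highest other 26). In QuantSeq they were as large in 19 of 100 splits with cGas (20, highest other 25). For cGas loss they were as large in 53 of 100 in F/F (11, highest other 23) and 63 of 100 in F/+ hearts (9, highest other 21). Chance was thus not excluded for these counts. For 2 weeks minus 1 week they were as large in 15 of 60 splits (19, highest other 26). For the interaction 0 lists passed, so 100 of 100 splits were as large by construction (highest other 27). As said above, the counts of these differences between effects cannot test chance. By the share of splits alone, chance was excluded for the lists without cGas (22, as many in 1 of 35 splits, highest other 21). That is a margin of 1 list, and of these lists 2 passed with an estimated correlation and 0 by exact tests of scores.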

How the results depend on the processing

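Of the tests reported in this part, those with the atrial marker score as a covariate, without the 11-day libraries, with a robust prior and by exact permutation of list scores were chosen only after the result was seen. No paired analysis was possible because the labels give no numbers that pair libraries across groups.

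Without the filter on low counts, where more genes are tested, counts of called genes were 109 at 1 week, 201 at 11 days, 117 for 11 days minus 1 week, 1183 with cGas, 515 without cGas, 23 for the interaction, and 93 and 93 for cGas loss in F/F and F/+ hearts. DESeq2, also run without that filter, gave 45 at 1 week, 46 at 11 days, 16 for 11 days minus 1 week, 227 without cGas, and 3 and 3 for cGas loss. A fit of only the libraries compared gave 2 at 1 week, 1 at 11 days, 246 without cGas and 2 for cGas loss in F/F hearts. A 2-fold minimum, which removes small changes by construction, left 1734 at 2 weeks, 1055 for 2 weeks minus 1 week and 345 with cGas. Pool KIUC033 alone gave 349 at 2 weeks and pool KIUC035 alone, with fewer libraries, 4894. For 11 days minus 1 week limma-trend gave 1, and for 2 weeks minus 11 days the atrial covariate gave 1028. The 78 genes without cGas became 13 by limma-trend on deposited CPM, 10 by limma-voom, 21 without sex, 171 among males and 172 with the atrial covariate, and the 0 genes of cGas loss in F/+ hearts became 1 among males. Beyond more genes and the 2-fold minimum, the cause was not tested.

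Counts of lists fell with an estimated correlation to 0 at 1 week, 11 days and 2 weeks, to 0 in each of the 3 differences between times and for cGas loss in both genotypes, and to 3 with and 2 without cGas, as most of these lists had estimated correlations above the preset 0.01. On ranks camera gave 8 lists at 1 week and 3 for the interaction, without the filter 0 at 11 days, and without sex 3 at 11 days and 3 for the interaction. Exact tests on scores passed 0 lists at 1 week, without cGas and for cGas loss in either genotype, and 0 at 11 days, where no list could pass because 2 against 3 libraries give no p below 0.1. Between the kits, 185 genes in place of 607 were called by both with the same sign when only genes of at least 10 CPM were used, since fewer genes remain. Lmna, not called in QuantSeq, changed sign with cGas by limma-trend (0.0170), and without cGas in a fit of only the libraries compared (0.20), among males (0.19), by limma-trend (0.0916) and without F/F null replicate 2 (0.0374) or 3 (0.00882), its range without single libraries there being -0.21 to 0.0374. The cause was not tested.

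With single libraries left out, counts ranged from 3 to 9 at 1 week, 0 to 235 at 11 days, 3046 to 5261 at 2 weeks, 1130 to 2966 for 2 weeks minus 1 week, 2 to 13 for 11 days minus 1 week, and 337 to 3172 for 2 weeks minus 11 days. In QuantSeq they ranged from 190 to 1169 with cGas and 7 to 175 without. They were 0 to 0 for the interaction and for cGas loss in F/F and in F/+ hearts.

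Counts and kit comparisons stayed within 1.5 times their value (correlations within a fixed margin) in 129 other settings and moved in 51. In fits without a library they stayed so in 105 and moved in 33. For named genes 1276 values kept direction and side of the threshold in other settings, 24 gained and 56 lost a call and 4 changed sign. At 2 weeks the count lay between 4452 and 5958 in the settings not named above. No alternative chosen before the data were examined was left out. What these depths and numbers of libraries limit together was read from simulated counts, which do not separate them: 37 of 100 genes changed 2-fold were called at 11 days and 20 of 100 in the interaction, so 0 genes there do not show that effects are absent.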

Other observations

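No tests in this part were chosen only after the result was seen, but the levels of Esr1 and Gm15459 were picked out after their values were seen and are given without a test.

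Stress and cell death genes were also higher in F/F hearts at 2 weeks in NEBNext libraries (edgeR for genes, camera for lists). Of 22 immediate early genes 13 rose and 0 fell (13 when adjusted over the list alone; median log2 fold change 0.91), among them Fos by 2.64 ± 0.41 (edgeR adjusted p = 5.29e-05). Of 23 p53 targets and DNA damage genes 11 rose and 1 fell (13 and 1 when adjusted over the list alone; median 0.52), including Eda2r, a receptor gene, by 1.95 ± 0.33 and Cdkn1a by 1.27 ± 0.29 (edgeR adjusted p = 0.000117 and 0.00201). Genes of apoptosis, necroptosis and pyroptosis rose at 10 of 18 members (13 when adjusted over the list alone; median 0.83), including Casp4, an inflammatory caspase, by 2.08 ± 0.34 (edgeR adjusted p = 0.000104). Feedback genes of MAPK signalling rose at 7 of 16 (10 when adjusted over the list alone; median 0.71). In the integrated stress response list 9 of 25 rose and 2 fell (10 and 3 when adjusted over the list alone; median 0.27). Psat1, a gene of serine synthesis, rose by 2.65 ± 0.26 and the stress cytokine Gdf15 by 2.59 ± 0.47 (edgeR adjusted p = 5.74e-07 and 0.000238). Camera adjusted p for the 5 lists was 2.52e-06, 0.000786, 2.23e-05, 0.00435 and 0.0389, and with an estimated correlation the adjusted p = 0.242, 0.132, 0.132, 0.391 and 0.487.

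Other cell types and programs did not pass by camera at 2 weeks. Focal adhesion genes had a median of 0.29 with 6 of 25 members higher (5 when adjusted over the list alone; camera adjusted p = 0.0609), and neutrophil markers a median of 0.89 with 1 of 4 higher (camera adjusted p = 0.25). Muscle ubiquitin ligases, autophagy and lysosome genes went both ways, 3 of 20 higher and 3 lower (median -0.14, camera adjusted p = 0.43). The median was -0.16 for heat shock genes, -0.24 for circadian genes, -0.21 for mitochondrially encoded mRNAs, -0.66 for atrial markers and -0.14 for mural cell markers (camera adjusted p = 0.332, 0.227, 0.309, 0.388 and 0.354). It was 0.05 for epicardial, -0.38 for adipocyte, -0.45 for erythroid, 0.23 for B cell and -0.14 for Schwann cell markers (camera adjusted p = 0.344, 0.407, 0.43, 0.574 and 0.628). It was -0.01 for skeletal muscle genes, for which the test direction was higher (camera adjusted p = 0.926). In QuantSeq libraries with cGas, 6 of 22 p53 targets rose (6 when adjusted over the list alone; median 0.19). Of 16 heat shock genes 3 rose (Hspa1b, Hspa1a and Hsp90aa1) while their list had a median of -0.12 (camera adjusted p = 0.745).

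Esr1, part of whose sequence the Myh6MCM transgene carries, was read at 4993 ± 1547 CPM in F/F (n = 4) and 5403 ± 2001 in wild type hearts (n = 5) of 1 week. It was at 2245 ± 224 (n = 2) and 4188 ± 132 (n = 3) at 11 days, and 753 ± 354 (n = 5) and 2373 ± 1203 (n = 7) at 2 weeks. In the 4 QuantSeq groups its mean lay between 39.3 and 77.5 CPM.

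Gm15459, a gene model on chromosome 5, was either near 0 or well above it. In F/+ hearts with cGas it ran from 0.420 to 61.1 CPM and in F/F hearts with cGas from 0.744 to 51.8 CPM. In the 8 cGas null hearts its highest value was 1.03 CPM.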
